A study of Mus musculus with 2 samples.

How the data were processed

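RNA was measured by sequencing in mouse Extensively Self-Renewing Erythroblasts (ESREs), immature red cell precursors that keep dividing in culture, on a C57/bl6 background. The expansion group held proliferating ESREs and the maturation group held ESREs after 1 day of maturation, per the labels. RNA was extracted with a Qiagen RNeasy-type kit and libraries were made with a NextFlex kit from Bioo Scientific, per the labels' protocols, which give the molecule as total RNA. Whether poly(A) RNA was selected or ribosomal RNA removed is not given in the sources used here.

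The deposited values are FPKM, fragment numbers scaled by transcript length and by the mapped fragments of the library, 1 value per gene row and group, per the file headers. Cuffdiff 2.0.2 and the mouse build mm9 are named in the submitters' processing notes, while the aligner, the gene annotation and any filter are not given in the sources used here. The series text speaks of biological duplicates at each time point, but the table holds 1 value per group. Each value is treated here as the authors' pooled value for that group. Whether the duplicates were pooled is not given in the sources used here. No replicate values, counts, fragment totals, confidence bounds or quality status were used here. The depth is therefore unknown, no test between replicates could be made, and no p-value, SD or n accompanies any value below. FPKM depends on the modelled transcript length, so rows for very short RNAs take high and unstable values, and reads that fit several near-identical genes are divided among them by the authors' software. A gene's locus in the table can span several neighbouring genes that were assembled together. Start positions were counted from 0 in the table, since 190 of 190 microRNA rows compared had a span equal to their RefSeq length, and are given here counted from 1 on mm9.

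The table holds 25791 rows, each with its own gene symbol. A row counted as expressed when its FPKM was at least 1 in at least 1 group, which left 9263 rows. The log2 ratio of maturation over expansion was computed with a pseudocount of 1, so it understates the difference of weakly expressed genes, while folds are ratios of the FPKM values themselves. Rows with a log2 ratio of at least 1 or of -1 or less were counted as at least 2-fold higher or lower, as a description of size. Where a gene was listed at 0 in 1 group no fold was computed, because an exact 0 can be a failed estimate.

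Before the data were examined, 38 gene lists were fixed, and 944 list entries were looked up in the table. Of these, 933 matched by symbol, 7 by a RefSeq synonym and 1 by a RefSeq gene ID, and 3 (Hbb-b2, Ahsp and Tpsab1) had no row and were not analysed here. The RefSeq table describes GRCm38.p6 and was used for names only. The lists cover adult globins, embryonic and minor globins, heme synthesis and heme transport, iron uptake and handling, red cell membrane, skeleton and blood groups, late erythroid maturation, DNA replication and S phase, mitosis and G2/M, ribosome biogenesis, erythroid and hematopoietic transcription factors, globin switching regulators, and growth factor receptors and signalling. Further lists cover STAT5-responsive genes, glucocorticoid-induced genes, immediate early and ERK feedback genes, CDK inhibitors and cell cycle exit, the BCL2 family, autophagy and mitophagy, nuclear condensation and enucleation, replication-dependent histone genes, ribosomal proteins, oxidative phosphorylation, glycolysis, nucleotide and one-carbon synthesis, cholesterol synthesis, the ATF4 and amino acid response, antioxidant defence, chaperones, the proteasome and the interferon response. Markers of macrophages, mast cells and basophils, granulocytes, megakaryocytes and platelets, lymphocytes, stem and progenitor cells, endothelial and stromal cells, and hepatocytes were included for other cell types.

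For each list with at least 3 expressed members, the median log2 ratio was placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins (seed 1). A list was said to stand apart at a percentile of 97.5 or more or of 2.5 or less. The percentile describes the 2 deposited values per gene and is not a p-value. The named genes follow a rule fixed in advance. It takes the 12 highest and 12 lowest log2 ratios among rows with an FPKM of at least 10 in a group, the 10 highest FPKM values of each group, up to 4 members per list (5 for the 12 primary lists) with the largest absolute log2 ratio, and a fixed set of globin and erythroid genes. Some of these genes are not reported here; the text gives a selection, and says where a gene outside the rule was chosen after its values were seen.

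The list procedure was tested on simulated log2 ratios for the 9263 expressed rows of the maturation against expansion comparison, with 200 genes shifted by 1 on the log2 scale. The noise was independent for each gene, with a centre of -0.25 and an SD of 0.5. All 10 simulated lists of 20 shifted genes were placed apart in the right direction. Every member of such a list was shifted alike, so this does not bear on lists that lie much nearer the median of all rows. Of 300 unshifted lists 16 (5.33%) were placed apart, a share set by the percentile limits themselves. Real lists can hold genes that vary together or share reads, so the simulation does not give their rate of false calls. Of the 200 shifted genes, 102 passed the 2-fold limit in the simulated direction, with upward and downward shifts counted together. The negative centre puts that limit farther from upward shifts than from downward ones.

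Alternatives were other pseudocounts, other scalings between the groups, other filters on low values, the removal of small RNA rows, other fold limits, unmatched random lists and the mean in place of the median. Transcript sequences and lengths from GENCODE vM21 were used only for the tests of explanations in the closing part, by gene name. Computation used Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.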

Results

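The series compared ESREs in expansion with ESREs after 1 day of maturation, to follow gene expression as self-renewing erythroblasts begin to mature. There was 1 deposited value per gene for each of the 2 groups, so no difference below has a replicate check, and the sequencing depth is unknown. The summed FPKM was 411084 in expansion and 416690 in maturation. A single type of row took much of these sums, as microRNA, snoRNA and other small RNA rows held 16.8% of the summed FPKM in expansion and 23.2% in maturation. Within this class Mir689-1 alone was at 41205 and 62706 FPKM. The class was set by gene symbol and leaves out some short RNAs, such as Rn5s at 2453 and 6551 FPKM.

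After 1 day of maturation, globin, heme synthesis, red cell membrane and histone genes stood at higher FPKM, together with genes of DNA replication and mitosis. Genes of growth factor signalling, immediate early genes, cholesterol synthesis, glycolysis and ribosome biogenesis stood lower. Slc4a1, the red cell anion exchanger, was listed at 0.0744 FPKM in expansion and 18.0 in maturation, while Kit, the receptor for stem cell factor, was at 16.8 and 1.40. Of the 9263 expressed rows, 290 were at least 2-fold higher in maturation, 621 were at least 2-fold lower and 8352 lay within 2-fold. The median log2 ratio of all expressed rows was -0.25, and once ratios were centred on it the split became 420 higher and 363 lower. List medians are therefore given as deposited and can be read against -0.25. Across the expressed rows, which are not independent replicates, log2(FPKM + 1) in the 2 groups had a Pearson r of 0.941.

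**Figure D1:**
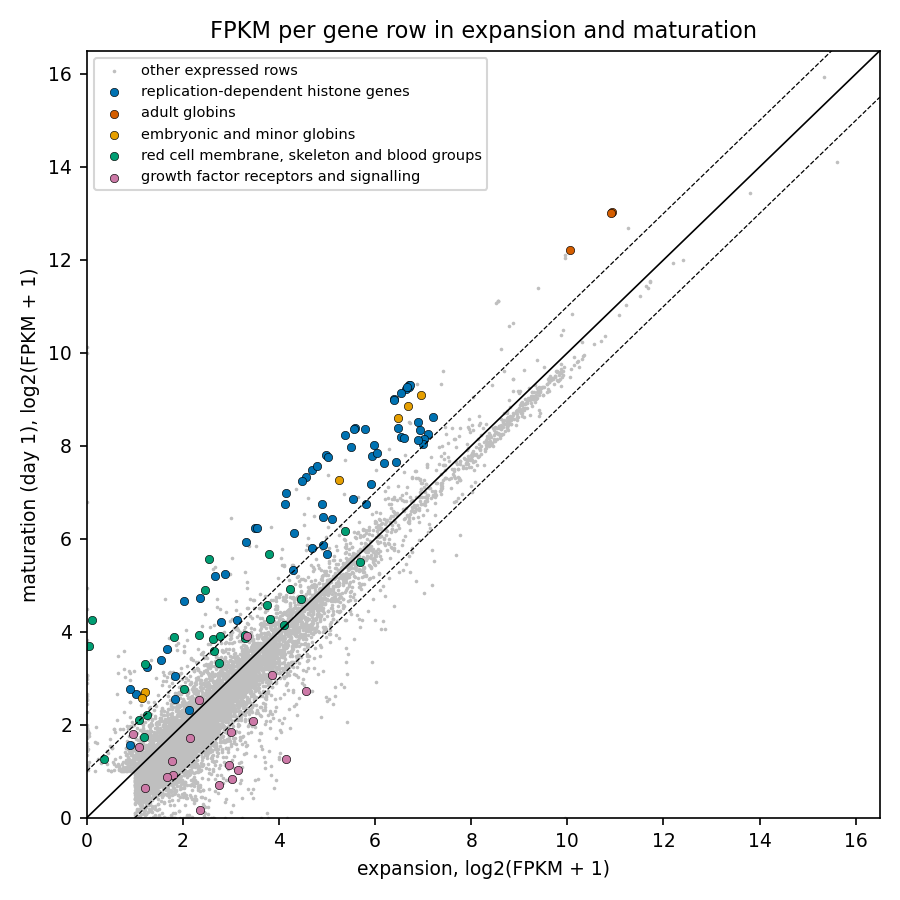
Each point is 1 expressed gene row, with log2(FPKM + 1) in expansion on the x axis and in maturation on the y axis. The solid line marks equal values and the dashed lines a 2-fold difference; all 9 globin rows and 59 of the 65 histone rows lie above the lines, and 9 of the 19 measured growth factor receptor and signalling genes lie below them.

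Hemoglobin genes were about 4-fold higher in maturation. Hba-a1 and Hba-a2, the adult alpha globins on chromosome 11 (mm9 32183672 to 32184486 and 32196492 to 32197310), were at 1951 FPKM in expansion and 8370 in maturation, and at 1929 and 8276. Hbb-b1, an adult beta globin on chromosome 7 (110961042 to 110962437), was at 1059 and 4739 FPKM. All 3 rows of the adult globin list were at least 2-fold higher, with a median log2 ratio of 2.10 at percentile 99.3 of matched random lists. The rows of the embryonic genes had values in both groups and differed by similar folds. Hbb-bh1 was at 123 and 544 FPKM (4.43-fold), Hbb-y at 102 and 465 FPKM (4.54-fold), and Hba-x, the embryonic zeta-like globin, at 37.2 and 154 FPKM (4.13-fold). Gm5736, the row of Hbb-bh2, was at 87.5 and 390 FPKM, and the theta-like row Hbq1 at 1.32 and 5.51 FPKM. All 6 rows of the embryonic and minor globin list were at least 2-fold higher, with a median of 2.08 at percentile 100. Hbb-bh1 equalled 11.6% of Hbb-b1 in expansion and 11.5% in maturation, Hbb-y 9.66% and 9.80%, and Hba-x 1.91% and 1.84% of Hba-a1. Each percentage is against 1 adult row and would be lower against all adult rows of its kind. LOC100503605, a further adult beta row outside the fixed list, stood at 94.1% of Hbb-b1 in expansion and 92.6% in maturation. The 9 globin rows together held 1.29% of the summed FPKM in expansion and 5.51% in maturation. Over 12 rows, with further globin rows chosen after the data were seen, the shares were 1.93% and 8.23%. Hba-a1 and Hba-a2 are near-identical and can share reads, and their summed FPKM was 4.29-fold higher. Reads of 36 bases shared with the adult beta globins could supply 89.7% of the Hbb-bh1 row in the group with the lower result. Reads of 50 bases could supply 2.97% and reads of 75 bases 0%. The read length is not given in the sources used here, so the level and proportion of Hbb-bh1 are uncertain. LOC100503605, which RefSeq names Hbb-bs, and Gm5226, an alpha globin pseudogene, were among the highest rows of maturation at 4390 and 4244 FPKM. LOC100503605, Hbb-bh1 and Gm5736 are listed at the same locus (110967782 to 110991676), so reads may be divided among them.

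**Figure D2:**
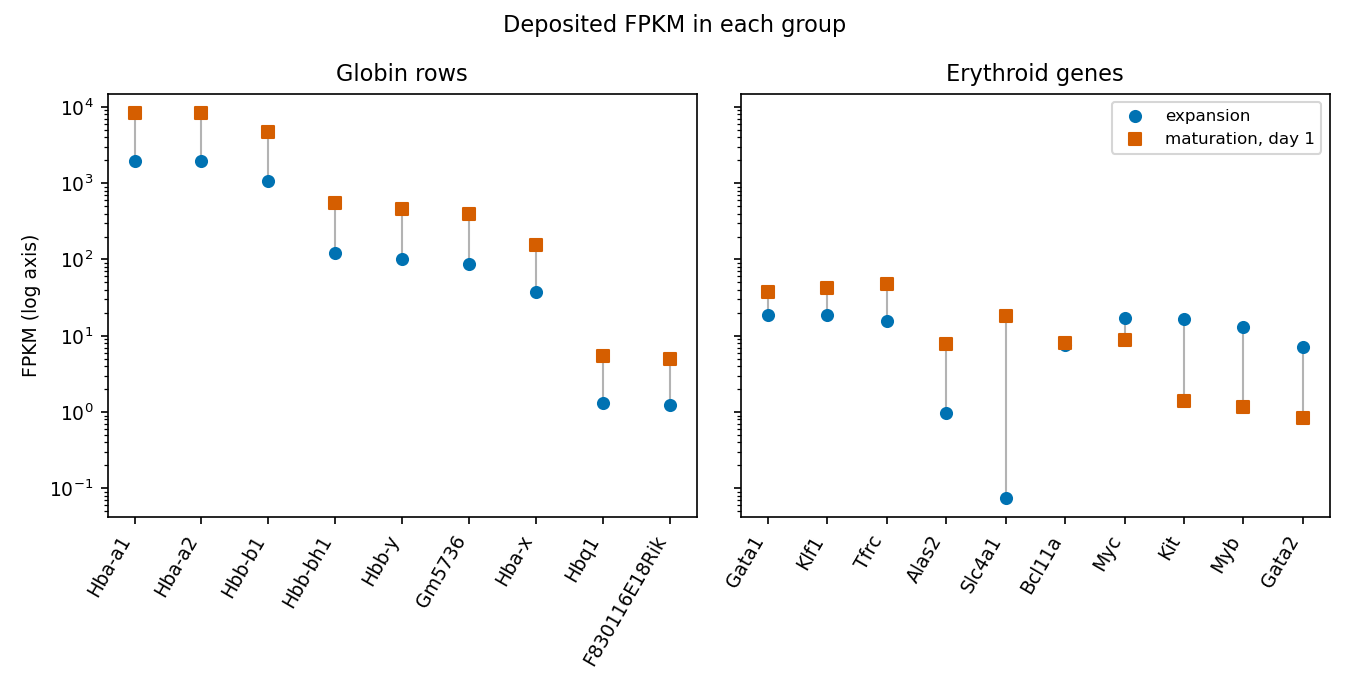
FPKM on a log axis for 9 globin rows (left) and 10 erythroid genes (right), with circles for expansion and squares for maturation, 1 deposited value each. The 9 globin rows differ by 4.03-fold to 4.54-fold, while Slc4a1 differs from 0.0744 to 18.0 FPKM and Bcl11a from 7.53 to 8.01 FPKM.

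Heme synthesis and transport genes were higher as a group. Of 16 measured members, 10 were at least 2-fold higher and none at least 2-fold lower, with a median log2 ratio of 1.20 at percentile 100. Alas2, the erythroid enzyme of the first step of heme synthesis, was at 0.975 FPKM in expansion and 7.89 in maturation (8.10-fold). Alad was at 9.38 and 56.9 FPKM, Uros at 3.18 and 15.4, and Tmem14c, a mitochondrial porphyrin transport protein, at 39.6 and 125. Iron genes were mixed, as 3 of 24 measured members were at least 2-fold higher and 1 at least 2-fold lower. The iron list median was 0.03, at percentile 98.6, with 18 of 24 members above the median of all expressed rows. Its higher members were Slc25a37, the mitochondrial iron importer mitoferrin 1, at 2.11 and 24.9 FPKM, Tfrc, the transferrin receptor, at 15.5 and 47.1 FPKM, and Glrx5 at 37.5 and 76.4 FPKM. Hmox1, which degrades heme, was lower, at 4.99 and 1.73 FPKM. Without a filter on low values the iron list median was -0.047, at percentile 92.6.

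Red cell membrane genes included Slc4a1 and Epb4.9, the largest folds among expressed list members with a value above 0 in both groups (242-fold and 332-fold). Of 26 measured members, 11 were at least 2-fold higher and none at least 2-fold lower, with a median of 0.92 at percentile 100. Epb4.9, which encodes the actin-bundling protein dematin, was at 0.0361 FPKM in expansion and 11.99 in maturation. Rhd was at 4.81 and 46.1 FPKM, Aqp1 at 4.51 and 29.1, and Epb4.2 at 1.30 and 8.86. The late erythroid list had 11 of 24 measured members at least 2-fold higher and 1 at least 2-fold lower, with a median of 0.60 at percentile 100. Hemgn was at 7.14 and 47.0 FPKM, Ube2l6 at 0.546 and 5.33, Slc6a9, a glycine transporter, at 2.65 and 11.2, and Tspan33 at 9.10 and 32.4. Bnip3l, a mitophagy receptor, was at 12.3 and 14.5 FPKM.

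Genes of DNA replication and mitosis were higher. All 34 measured genes of DNA replication and S phase had a log2 ratio above 0, and 7 were at least 2-fold higher, with a median of 0.76 at percentile 100. Ccne1, which encodes cyclin E1, was at 2.60 and 12.2 FPKM, Rrm2, a subunit of ribonucleotide reductase, at 25.5 and 89.0, Cdc6 at 3.49 and 9.90, and Slbp, the histone stem-loop binding protein, at 14.8 and 34.8. Of 39 measured mitosis and G2/M genes, 38 had a log2 ratio above 0 and 6 were at least 2-fold higher, with a median of 0.59 at percentile 100. Birc5 was at 16.1 and 42.4 FPKM, Ccna2 at 16.1 and 41.6, and Mki67 at 23.0 and 57.3. After centring on the median of all expressed rows, 17 of the 34 S phase genes and 13 of the 39 mitosis genes were at least 2-fold higher. Replication-dependent histone genes were higher still, with 59 of 65 at least 2-fold higher, none lower and a median of 1.86 at percentile 100. Hist1h2bn was at 40.7 and 299 FPKM and Hist1h2bb at 16.7 and 126 FPKM, and many histone copies are near-identical and can share reads. Histone rows were 59 of the 290 rows at least 2-fold higher. Other RNAs that lack a poly(A) tail, in groups chosen after the values were seen, were mixed. Of 19 small nuclear, U3, 7SK, RNase P, RNase MRP and 5S rows 18 were at least 2-fold higher, with a median of 2.21, whereas of 63 other snoRNA rows 13 were at least 2-fold higher and 10 lower, with a median of -0.01. Several of the 19 rows are copies of the same RNA, such as 5 rows of U3, and can share reads. CDK inhibitors and cell cycle exit genes did not stand apart (18 measured, 1 higher and 2 lower by at least 2-fold, median -0.48, percentile 5.12), although they lay at percentile 0.32 with a pseudocount of 5 and at 1.44 when random lists were not matched. After centring 2 were at least 2-fold higher and 1 lower. Cdkn2c was at 1.47 and 4.11 FPKM, and Cdkn2a at 8.88 and 2.12 FPKM.

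Among 29 measured erythroid and hematopoietic transcription factors, 5 were at least 2-fold higher and 6 at least 2-fold lower, and the list did not stand apart (median -0.40, percentile 2.59). After centring these counts were 7 and 3. Gata1 was at 18.8 FPKM in expansion and 37.4 in maturation, and Klf1 at 18.7 and 42.7. E2f2 was at 3.04 and 11.96 FPKM and Klf3 at 2.04 and 7.47. In the other direction Gata2 was at 7.20 and 0.824 FPKM, Myb at 13.2 and 1.17, Stat5a at 10.001 and 3.21, and Myc at 17.1 and 8.84. Of 20 measured globin switching regulators, 2 were at least 2-fold higher, 2 at least 2-fold lower and the median was -0.23, at percentile 43.2. Bcl11a, a repressor of embryonic globins, was at 7.53 and 8.01 FPKM (1.06-fold). Sox6 was at 0.136 and 2.86 FPKM and Ehmt2 at 6.43 and 1.83 FPKM.

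Growth factor receptor and signalling genes were lower, with 9 of 19 measured members at least 2-fold lower, none at least 2-fold higher and a median of -0.86 at percentile 0. Besides Kit these were led by Csf2rb at 7.12 and 0.772 FPKM, Dok2 at 4.15 and 0.125, Lyn at 7.82 and 1.03, and Pik3cd at 5.73 and 0.634. Epor, the erythropoietin receptor, was at 9.12 and 13.9 FPKM. Immediate early and ERK feedback genes had 8 of 12 measured members at least 2-fold lower and 1 higher, with a median of -1.33 at percentile 0. Egr1 was at 12.5 and 0.0804 FPKM, Ier2 at 11.3 and 1.92, and Spred2 at 3.03 and 0.370, whereas Dusp1 was at 1.997 and 7.74. Of 12 measured glucocorticoid-induced genes 5 were at least 2-fold lower and 3 higher, with a median of -0.57 at percentile 0.42, a position lost with no filter (33.7), a minimum FPKM of 5 (3.87) or the mean (2.98). Zfp36l2, which encodes an RNA-binding protein, was at 64.1 and 6.54 FPKM, Ddit4 at 12.1 and 1.30, and Per1 at 5.52 and 1.53. STAT5-responsive genes had a median of 0.11 at percentile 97.8, with 3 of 7 at least 2-fold higher and 1 lower, and lay at percentile 97.2 when random lists were not matched. Fam132b, which encodes the hormone erythroferrone, was at 0.563 and 10.2 FPKM, Cish at 5.53 and 25.2, Pim1 at 10.04 and 24.6, and Socs1 at 1.79 and 0.330.

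Ribosome biogenesis genes were lower by a smaller amount, as 34 of 35 had a log2 ratio below 0 and 1 was at least 2-fold lower, with a median of -0.62 at percentile 0. Of the 35, 28 lay below the median of all expressed rows, and none was at least 2-fold lower after centring. Rrp9 was at 7.85 and 3.31 FPKM and Ddx21 at 30.3 and 15.6. Cholesterol synthesis genes had 7 of 22 measured members at least 2-fold lower and none higher, with a median of -0.85 at percentile 0. Sc4mol was at 25.6 and 8.30 FPKM and Insig1 at 21.7 and 6.92. Glycolysis genes had 8 of 21 at least 2-fold lower and 1 higher, with a median of -0.61 at percentile 0.01, and 5 were at least 2-fold lower after centring. The muscle-type pyruvate kinase gene Pkm2 was at 35.1 and 6.01 FPKM, while the liver and red cell pyruvate kinase gene Pklr was at 8.79 and 38.2. Pgam1 was at 27.0 and 7.53 FPKM and Ldha at 106 and 38.1.

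Ribosomal protein genes lay close to the median of all expressed rows, with a list median of -0.27, at percentile 0.11, and no member beyond 2-fold among 64, and at percentile 36.02 when random lists were not matched. Rps20 was at 675 and 438 FPKM. The 81 oxidative phosphorylation genes had a median of 0.01 at percentile 99.2, none beyond 2-fold, and 72 above the median of all expressed rows. Their percentile was 96.1 with a minimum FPKM of 5 and 82.5 for the mean. Ndufa5 was at 16.6 and 24.7 FPKM and Cox6c at 152 and 91.0.

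The other process lists did not stand apart with the settings fixed in advance. The BCL2 family had a median of -0.35 at percentile 28, with 2 of 11 at least 2-fold lower, and Pmaip1 at 6.49 and 0.765 FPKM. Autophagy and mitophagy genes had a median of -0.18 at percentile 78.8, with 1 of 28 at least 2-fold higher, Wipi1 at 0.625 and 2.75 FPKM. Nuclear condensation and enucleation genes had a median of -0.12 at percentile 85.8, with 1 of 22 lower, Hdac5 at 3.05 and 0.896 FPKM. Nucleotide and one-carbon synthesis genes had a median of -0.26 at percentile 15.4, with 1 of 23 lower, Nme2 at 103 and 48.6 FPKM. ATF4 and amino acid response genes had a median of -0.24 at percentile 26.8, with 3 of 22 lower (1 higher and 1 lower after centring), among them Psat1 at 51.7 and 18.2 FPKM. Antioxidant defence genes had a median of -0.05 at percentile 83.3, with 2 of 22 higher, among them Prdx2, a peroxiredoxin abundant in red cells, at 77.7 and 244 FPKM, and lay at percentile 98.0 when random lists were not matched. Chaperone genes had a median of -0.27 at percentile 4.32, with none of 23 beyond 2-fold, and Hsp90ab1 at 255 and 139 FPKM. Proteasome genes had a median of 0.00 at percentile 94.0, with 1 of 35 lower, the immunoproteasome subunit Psmb8 at 4.31 and 0.362 FPKM. They lay at percentile 97.6 with no filter on low values and at 99.9 when random lists were not matched. The 3 measured interferon response genes had a median of -0.63 at percentile 12.9, and Bst2 was at 12.7 and 5.43 FPKM.

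**Figure D3:**
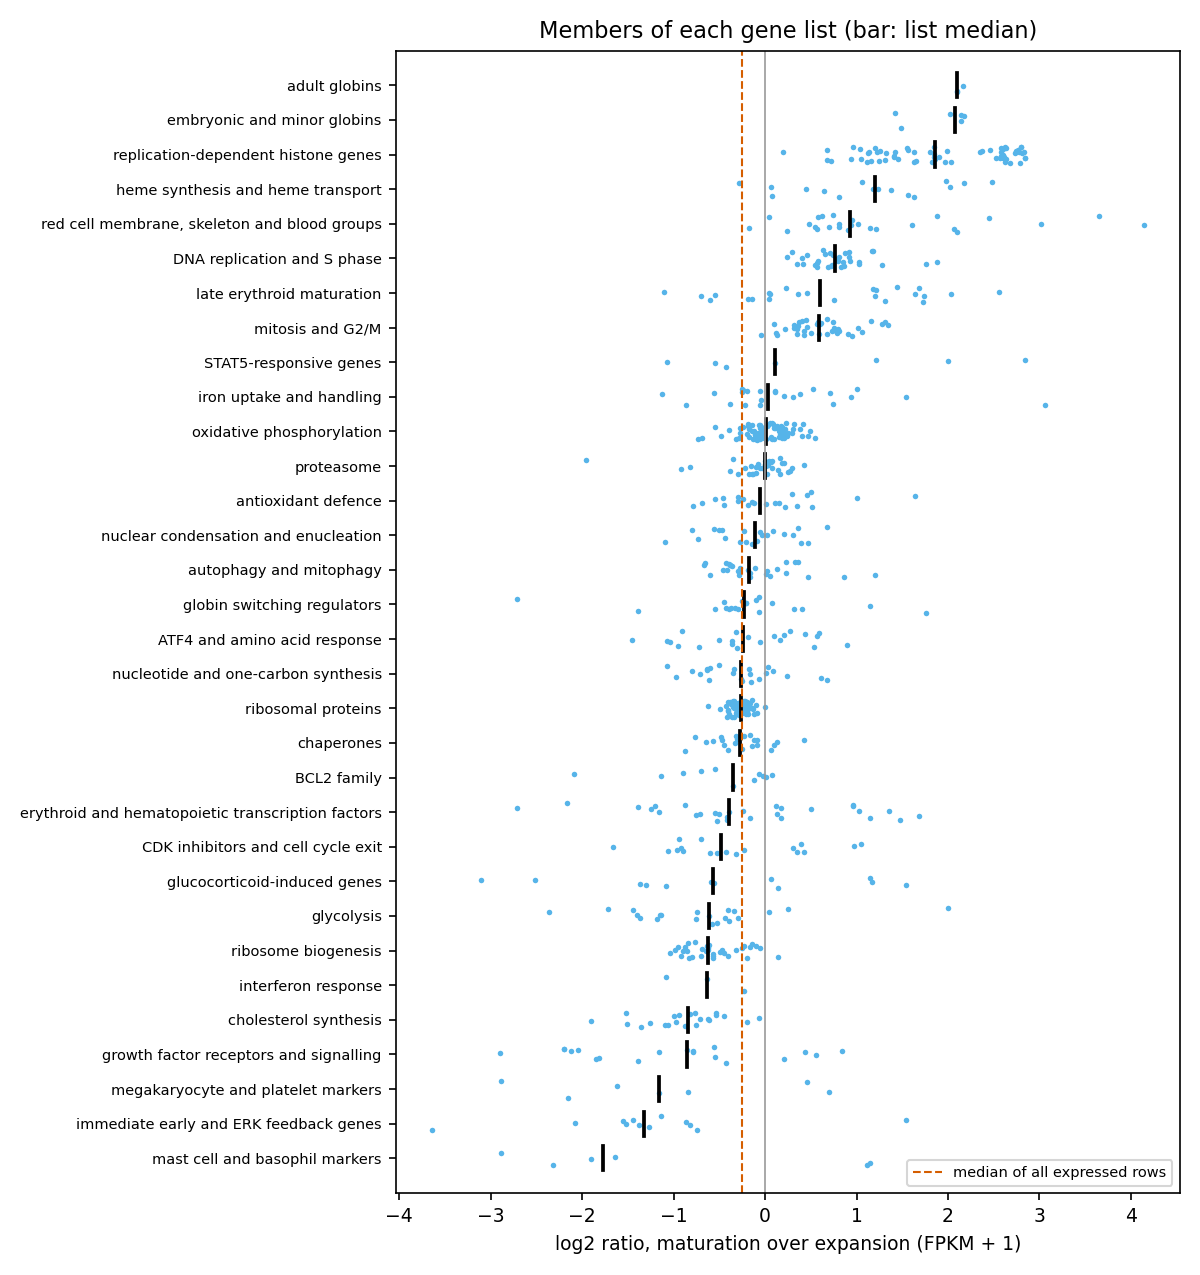
Each row is a gene list with at least 3 measured members and each point a measured member, placed by its log2 ratio of maturation over expansion from FPKM + 1, with a black bar at the list median. The dashed line at -0.25 is the median of all expressed rows; the medians of these 32 lists run from -1.78 for mast cell and basophil markers to 2.10 for adult globins.

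Markers of other cell types were mostly absent or lower in maturation. Of the mast cell and basophil markers 6 were measured, 4 at least 2-fold lower and 2 higher, with a median of -1.78 at percentile 0. Ms4a2, a subunit of the IgE receptor, was at 7.07 and 0.0903 FPKM, Hdc at 4.47 and 0.0945, and Il1rl1 at 8.92 and 1.64. Of 7 measured megakaryocyte and platelet markers 4 were at least 2-fold lower and none higher, with a median of -1.16 at percentile 0.04. With no filter on low values, the mast cell list lay at percentile 87.5 and the megakaryocyte list at 67.1. Gp5 was at 9.63 and 0.438 FPKM, Gp1ba at 7.22 and 0.845, and Itga2b at 5.15 and 0.996. Cd68 was the 1 measured macrophage marker, at 1.18 and 0.539 FPKM, and Gata2 the 1 measured stem and progenitor marker. No granulocyte, lymphocyte, endothelial and stromal, or hepatocyte marker reached an FPKM of 1 in either group, so the count measured was 0 for each of these lists.

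Several of the largest log2 ratios belonged to rows listed at 0 in 1 group, for which no fold is given. There were 24 rows at 0 in 1 group and at least 5 FPKM in the other, 20 of them small RNA rows. Mir451 and Mir144, neighbouring erythroid microRNA genes on chromosome 11 (77886672 to 77886743 and 77886507 to 77886572), were listed at 0 in expansion and at 111 and 29.9 FPKM in maturation. Snord95, Snord43 and Mir142 were listed at 0 in expansion and at 21.4, 13.2 and 11.4 FPKM in maturation, and Snord57 was at 6.96 and 86.5. Lars2 was at 983 FPKM in expansion and listed at 0 in maturation, and Snora24, Mir707 and LOC100504435 were at 16.9, 12.7 and 11.3 FPKM and then listed at 0. LOC100503946, a pseudogene, and LOC100503984 share a locus on chromosome 1 (24600631 to 24647157) and were listed at 0 in expansion and at 1018 and 1116 FPKM in maturation. Besides Egr1, Kit and Zfp36l2, the lowest ratios belonged to Cmtm7 at 41.9 and 3.16 FPKM, Rcsd1 at 13.9 and 0.566, Phlda2 at 14.3 and 0.771, Glipr1 at 10.1 and 0.352, and Sept9 at 13.3 and 0.893.

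The 3 highest FPKM values of each group belonged to non-coding rows, and Hba-a1 and Hba-a2 came next in maturation. LOC236598, which RefSeq names as 28S ribosomal RNA, was at 49975 FPKM in expansion and 17620 in maturation, Mir689-1 at 41205 and 62706, and Mir703 at 14271 and 11163. Rn5s, the 5S ribosomal RNA row, was at 2453 and 6551 FPKM. These rows weigh heavily in the summed FPKM, and they say little of the messenger RNA.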

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

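With 1 value per gene and group no setting has a replicate error. The count of genes at least 2-fold lower, 621, became 1303 with a pseudocount of 0.1, 363 after centring on the median of expressed genes and 349 with a minimum FPKM of 5. With a pseudocount of 5 there were 166 higher and 148 lower, with a fold of 1.5 there were 584 and 1886, and with a fold of 4 there were 98 and 98. These differences follow from the settings themselves, since each changes the ratio, the limit or the rows that are counted. The iron list median became -0.047, at percentile 92.6, with no filter on low values, and the cause was not tested. The 3 scalings move all genes nearly alike, so they hardly bear on where a list lies among random lists. Over the other alternatives run on the 32 lists with at least 3 measured members, 207 comparisons kept their side of the percentile limits, 5 newly passed them, 10 no longer did and none moved from above the random lists to below them or the reverse. For the 170 genes named by the rule, 785 comparisons kept their side of 2-fold, 17 newly passed it and 48 no longer did. None of those at least 2-fold changed sign, but these settings could not have made them do so. A pseudocount keeps the sign of a ratio, and the scalings moved ratios by much less than 2-fold. Mast cell and basophil markers, and megakaryocyte and platelet markers, did not stand apart without a filter on low values, which adds members near 0. With further globin rows, an alternative chosen after seeing the data, the globin share was 1.93% in expansion and 8.23% in maturation. Filtering by the authors' status or intervals, a share by fragments and leaving out duplicates were not run, because no such columns were used here. Taking 1 row per symbol moves nothing, since each symbol has 1 row. No paired analysis was possible because each group has 1 value.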

Other observations

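The gene groups in this paragraph were chosen after the values were seen, so their medians describe the chosen genes and test nothing. Actin and its regulators were lower in maturation, with 18 of 33 measured members at least 2-fold lower, none higher and a median log2 ratio of -1.01. MHC class I and peptide loading genes had a median of -0.81, with 3 of 22 at least 2-fold lower. Tubulin genes went the other way, with 4 of 17 at least 2-fold higher and a median of 0.52, among them Tuba4a at 23.3 and 63.5 FPKM and Tuba8 at 9.49 and 25.1. Many tubulin rows, and many H2 rows of the MHC class I group, are close relatives that can share reads. Their counts are therefore not counts of independent genes. The D cyclins differed, as Ccnd3 was at 13.3 and 75.6 FPKM and Ccnd2 at 10.7 and 3.97. Mgst3 was at 10.5 and 56.3 FPKM, Hebp1, a heme-binding protein gene, at 6.91 and 36.7, Smox at 0.830 and 7.90, and Srgn, which encodes a granule proteoglycan, at 128 and 27.8. Both groups had Y-linked transcripts at similar levels, with Eif2s3y at 17.5 and 17.2 FPKM and Ddx3y at 9.65 and 8.28, while Xist was at 0.00363 and 0.0254.

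Of the tests below, those of Hba-x, Hbq1 and Hbq1b and of the alpha globin pseudogene for shared reads were written before their results were seen. The beta-like rows were first tested together, also before their result was seen, and that joint test decided nothing, so Hbb-bh1 was then separated from Hbb-y and Hbb-bh2 after the result. The tests of maturing cells, histone genes and other cell types were chosen after the values were seen.

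Embryonic, minor and adult globin rows kept nearly constant proportions while all 9 were 4.03-fold to 4.54-fold higher. Reads shared with the abundant adult genes may be a cause, and it was tested by the windows of 36, 50 and 75 bases that occur in adult globin transcripts with up to 2 mismatches, counted at the full adult FPKM. Each percentage is for the group with the lower result, and for beta-like rows the adult FPKM was that of Hbb-b1 and LOC100503605. Such windows could supply 0% of Hba-x, Hbq1, Hbq1b and Hbb-bh2, and 19.7% of Hbb-y at 36 bases. This argues against reads shared with up to 2 mismatches as the main source of Hba-x, Hbq1, Hbq1b and Hbb-y. Hbq1 and Hbq1b were at only 1.32 and 1.23 FPKM in expansion, beside 1951 for Hba-a1. For these rows the windows cannot exclude a very small share of adult reads placed with more mismatches. Hbb-bh2 stays open, because its row Gm5736 is listed at the same locus as Hbb-bh1 and LOC100503605. A window test cannot exclude reads divided among rows of a shared locus. At 36 bases the windows could supply 89.7% of Hbb-bh1 and 83.7% of the pseudogene row Gm5226. At 50 bases they could supply 2.97% and 26.6%, and at 75 bases 0% of either row. These stay open because the read length is not given in the sources used here. Maturing cells already present in the expansion culture would need a share of 22.0% to 24.8%, and of 2066 rows at 10 FPKM or more in maturation and above 0 in expansion, small RNA and histone rows left out, 6 were under 0.5 of the expansion level that share would bring: Epb4.9 at 0.0361 against 2.64 FPKM, Slc4a1 at 0.0744 against 3.96, Fam132b at 0.563 against 2.25, Slc38a5 at 0.704 against 2.41, Slc25a37 at 2.11 against 5.49 and Rhd at 4.81 against 10.2. The first pair, far below that level, argue against cells with the full maturation profile as the whole source, while the other 4 fall short by less, and cells at an intermediate stage and a joint increase of all globin genes with maturation stay open and untested.

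Replication-dependent histone genes were higher in every family, with summed FPKM 7.12-fold higher for H2B, 6.08-fold for H4, 4.55-fold for H1, 3.20-fold for H3 and 2.27-fold for H2A. A bias toward transcripts under 700 bases in the maturation libraries, large enough to give the histone list median of 1.86, is argued against. The 136 non-histone protein-coding genes with a longest transcript under 700 bases had a median log2 ratio of -0.087 (95% bootstrap interval over genes -0.16 to 0.02). By the same measure 39 of the 65 histone rows are under 700 bases, so the lengths of the others are not matched. The interval treats genes as independent. It lies above the median of all expressed rows, -0.25, so a smaller bias toward short transcripts stays open. More retained RNA without a poly(A) tail cannot be told apart from a biological difference, because 19 independently transcribed rows (small nuclear RNAs, the snoRNA U3, 7SK, RNase P, RNase MRP and 5S) had a median of 2.21, or 1.79 over the 14 without U3, while 63 other snoRNA rows had a median of -0.01. Some of the 19 rows are copies of the same RNA and can share reads. S phase genes, whose messages carry poly(A) tails, were also higher, with a median of 0.76, and a larger share of cells in S phase after 1 day of maturation stays open and untested.

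Some mast cell, basophil, megakaryocyte and platelet genes were lower in maturation, and a loss of such cells from the culture is a candidate explanation. In expansion the highest of Cpa3, Cma1, Mcpt4, Tpsb2, Mcpt8 and Prss34, abundant in mast cells or basophils, was 0.192 FPKM, against 7.07 for Ms4a2, and the highest of Pf4, Ppbp, Vwf and Gp1bb, abundant in megakaryocytes and platelets, was 0.0333 FPKM, against 9.63 for Gp5. These genes were picked after their values were seen. Other markers of the same lists were present in expansion, with Hdc at 4.47 FPKM, Il1rl1 at 8.92, Gp1ba at 7.22 and Itga2b at 5.15. The values therefore show only that the picked genes were near 0. They do not decide whether mast cells, basophils or megakaryocytes were the source of Ms4a2 and Gp5. Some list members were higher in maturation, with Mcpt1 at 0.0139 and 1.20 FPKM, Mcpt2 at 0.0406 and 1.30, Tubb1 at 13.1 and 18.3, and Gp9 at 0.756 and 1.84. Expression of these genes by the immature erythroblasts themselves, lower with maturation, is a hypothesis that was not tested.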
